A study of Mus musculus with 120 samples.

How the data were processed

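RNA from mouse soleus muscle and heart was measured by sequencing of mRNA enriched with oligo(dT), on paired-end libraries of the NEBNext Ultra II kit, per the labels' protocols. The labels cover 120 samples, 60 per tissue. The authors deposited a table per tissue of expected counts per gene, which need not be whole numbers. Per the submitters' processing notes, STAR 2.5.2b, RSEM 1.2.28 and the mouse genome build mm10 were used, and which setting each tool had is not given in the sources used here. The labels do not say that the strand of the RNA was kept, so overlapping and antisense genes, and genes with near-identical copies elsewhere, are uncertain. Deposited FPKM values were not used here.

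Columns were tied to samples by the mouse code in their names. In this way 96 libraries were placed, 48 per tissue, in 16 groups of 6 (4 strains, exercised or non-exercised, 2 tissues). Another 24 columns carried names that matched no sample title and were not used, so the control strain is not analysed here. The comparisons that had been planned against that strain, and the relation between mutant effects measured against it, were replaced by comparisons between the mutant strains. These replacements were chosen after the column names were seen. The mean of the 3 strains with a mutation in mitochondrial DNA (mtDNA) served as the reference for the strain that lacks ANT1.

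The deposited expected counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr by group, which left 13935 of 53656 genes in soleus, 15723 in heart, 13843 in the exercised soleus libraries with a response class and 16172 over both tissues. Library sizes were scaled by TMM. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with all libraries of a tissue in a fit and a mean per group, and p-values were adjusted by Benjamini and Hochberg's method per comparison. A gene was called at an adjusted p under 0.05. Every adjusted p of a gene is from this test unless another tool is named. Log2 CPM of single libraries used a prior count of 2. Levels in CPM and log2 CPM are scaled to the library size times its TMM factor. A level in CPM is therefore not a share of the counts of its library. By the mouse codes in the titles, the libraries of a tissue come from separate mice, and 19 codes occur in both tissues. Strain comparisons used the non-exercised mice, 6 against 18 for ANT1 and 6 against 6 for pairs of mtDNA strains. Training was tested within each strain, on average over the 4 strains, and for a difference between strains. Responders were compared with non-responders among exercised soleus samples, 3 against 3 per strain and averaged over strains. A strain difference in soleus minus that in heart was tested over both tissues.

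Gene lists, 42 in all, were fixed before the data were examined, as were the tests and the main set of alternatives. Each list with at least 5 tested genes was tested with cameraPR in limma 3.58.1 on the signed z of the edgeR test, at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. An estimated correlation (camera) and a rotation test of the list itself (fry) were alternatives. A list test at the preset correlation takes genes of a list as nearly independent, which they were not in these libraries, so the adjusted p with an estimated correlation stands beside it. Counts "adjusted over the list alone" use the genes of that list only.

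The genes named were chosen by a rule written before the data were examined. It takes Slc25a4, mt-Nd5, mt-Nd6, mt-Co1 and Nnt whatever their change, the 8 genes with the smallest p in each direction among called genes with an average log2 CPM of at least 1, and the 4 members of each list with the smallest p. Predicted genes, pseudogenes and clone names, recognized by the form of the name, were left out of the rule, and names of the RP23 and RP24 clone libraries were treated as clone names. The text names fewer of these. Kcnk3, Adipoq, Plin1, Fgf12, Bmpr1b, Chrng, Mstn and Gdf15 stood near 0 in at least 1 compared group, so the size of their log2 difference rests on few counts there. A gene named outside the rule is said to have been chosen after its values were seen.

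Library totals and the share of counts from mtDNA were compared by exact two-sided permutation tests of group means, 16 tests in all, adjusted together. Among pairs of libraries of a group, 120 per tissue, 0 were identical, and the smallest chi-square per gene was 7.14 in soleus and 6.77 in heart, so no library was counted as a repeat. For 1 of 19 shared mouse codes, B80, the labels exclude each other (exercised in soleus, non-exercised in heart), so its libraries may not be of the same mouse. Over 7267 genes, the deviations of their soleus and heart libraries from the group means had a median correlation of 0.129 (lowest -0.388, highest 0.487), and 11 of 19 were over 0.1. Because libraries with the same code were taken to come from the same mouse, B80 included, a fit with the mouse as a block was made with limma voom, whose estimated correlation within a mouse was 0.0376. Positions of genes were taken by symbol from an annotation of the same build (GENCODE M21, GRCm38), which holds 28534 of the 53656 names.

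Alternatives were RLE scaling in place of TMM, DESeq2 1.42.0, no filter on low counts, a fit on the compared groups only, exercised mice or both arms in place of non-exercised mice, the mouse as a block, each replicate left out in turn for the response classes, and the libraries of mouse B80 left out. Alternatives chosen after seeing the data were the Myh4 level as a covariate in soleus, an atrial score alone or with adipocyte and red cell scores as covariates in heart, ANT1 libraries A81 and A82 left out, mtDNA-encoded genes left out before scaling, and each soleus and heart library left out in turn for the strain and training comparisons. Exercise capacity and ejection fraction of single mice were not used here.

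The procedure was tested on simulated counts with 200 changed genes drawn from the real means and library sizes. The changed genes were taken among those with an average log2 CPM of at least 1. At 2-fold and 4-fold changes edgeR recovered 96% and 100% of them for ANT1 in soleus (13935 genes, 3.45% of calls false), 94% and 100% for ND5 against ND6 in soleus (3.96% false) and 93% and 98% for training of ND5 in soleus (3.05% false). In heart (15723 genes) it recovered 85% and 99% for ANT1 (3.16% false), 80% and 96% for ND5 against ND6 (5.88% false) and 77% and 93% for training of ND5 (4.49% false). Responders against non-responders gave 98% and 100% on average (13843 genes, 6.60% false) and 78% and 100% in ND5 alone (3.78% false). The tissue difference of ANT1 gave 77% and 96% (16172 genes, 4.95% false). With DESeq2 the false share was higher in all of these, from 5.83% for ND5 against ND6 in soleus to 14.8% for the same strains in heart, 11.9% for training of ND5 in heart, 13.2% for responders on average and 11.2% in ND5 alone, so its counts hold more false calls. The list test called the changed list in each of these 9 simulations and 0 of 19 unchanged lists of 20 genes. The simulated genes were drawn independently of each other, so this cannot show how often the list test is wrong for correlated genes.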

Results

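The series asks how mitochondrial mutations act on the response to endurance training. Gene expression was measured in the soleus, a slow postural muscle, and in the heart of 4 mutant mouse strains on the C57BL/6EiJ background. ND5, ND6 and CO1 mice carry a missense mutation in mtDNA, at position 12352 (complex I subunit ND5), 13997 (complex I subunit ND6) and 6589 (complex IV subunit CO1). ANT1 mice lack Slc25a4, which encodes the adenine nucleotide translocator that exchanges ATP and ADP across the inner mitochondrial membrane in heart and muscle. From 16 weeks of age mice ran on every 2nd day for 45 min at 50% of their maximal capacity for 8 weeks, or were handled without training, and tissues were taken 6 days after the last session. Each strain, treatment and tissue had 6 libraries. Totals ranged from 10.2 to 20.7 M counts in soleus (mean 14.7 M, where M stands for mega) and from 19.7 to 26.5 M in heart (mean 23.1). Non-exercised ND5 soleus libraries had the lowest mean total, 12.3 M, which was below ND6 by 4.47 M (exact permutation p = 0.013, adjusted p = 0.0416) and below CO1 by 3.57 M (exact permutation p = 0.00866, adjusted p = 0.0346). The control strain of the series was not analysed here, so each strain difference is a difference between mutants.

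Slc25a4 was nearly absent from ANT1 mice. In soleus its level was 14.5 CPM ± 4.07 (SD, n = 6) in non-exercised ANT1 mice and 10.6 CPM ± 3.78 in exercised ones, against 2730 CPM ± 462 in ND5, 3355 CPM ± 190 in ND6 and 3189 CPM ± 327 in CO1 non-exercised mice, and 3197, 3315 and 3441 CPM in the exercised mice of those strains. In heart it was 4.24 CPM ± 1.56 and 2.35 CPM ± 0.446 in non-exercised and exercised ANT1 mice, against 2595 CPM ± 1276 in ND5, 3080 CPM ± 780 in ND6 and 3656 CPM ± 175 in CO1 non-exercised mice, and 2775, 2523 and 3471 CPM in the exercised ones. All 24 ANT1 libraries lay below all 72 others. Slc25a4 lies on chromosome 8 of mm10, from 46206797 to 46211284 on the minus strand. The lowest library of the mtDNA strains was the heart of ND5 mouse B80 (8.92 on the log2 CPM scale, the other hearts up to 11.94).

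Transcripts encoded by mtDNA took a larger share of the RNA in ANT1 mice. In non-exercised soleus they made up 39.0% of counts ± 4.34 (SD, n = 6) in ANT1, against 15.7% ± 2.17 in ND5, 20.7% ± 1.32 in ND6 and 18.5% ± 1.71 in CO1. The difference of 20.7 percentage points from the mtDNA strains had an exact permutation p of 7.43e-06, the smallest that 134596 arrangements allow (adjusted p = 0.000119). In heart the shares were 33.7% ± 4.41 in ANT1, 21.7% ± 7.72 in ND5, 26.3% ± 6.84 in ND6 and 27.8% ± 0.423 in CO1, a difference of 8.40 points (exact permutation p = 0.00587, adjusted p = 0.0313). Exercised mice had 37.9%, 18.5%, 20.8% and 19.8% in soleus and 31.3%, 23.5%, 23.7% and 27.3% in heart, in the order ANT1, ND5, ND6 and CO1. Among the mtDNA strains, ND5 soleus lay below ND6 by 5.03 points (exact permutation p = 0.00433, adjusted p = 0.0313). Its distance of -2.82 points from CO1 did not pass after adjustment (exact permutation p = 0.0368, adjusted p = 0.0736).

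**Figure D1:**
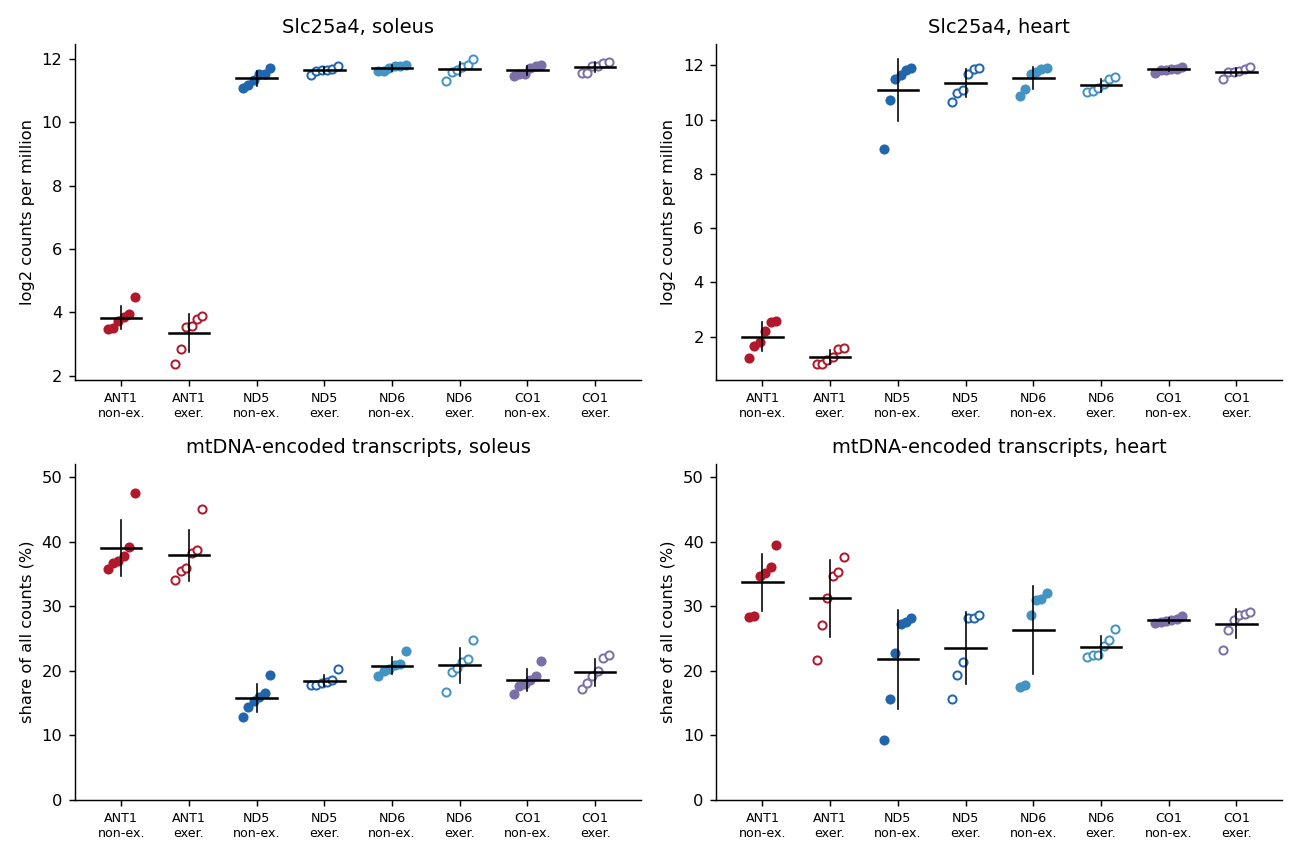
Slc25a4 level (log2 CPM, top) and share of counts from mtDNA-encoded transcripts (%, bottom) in each soleus and heart library by strain, with filled points for non-exercised and open points for exercised mice, bars at the mean and whiskers of 1 SD (n = 6). ANT1 soleus libraries lie between 2.36 and 4.48 for Slc25a4, and those of the mtDNA strains between 11.08 and 11.99.

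Strain differences at rest were examined first. In soleus, ANT1 mice differed from the mean of the 3 mtDNA strains in a broad rise of mitochondrial transcripts, together with lower matrix transcripts and lower levels of Actn3 and Sln. mt-Co1, the catalytic subunit of complex IV, stood at 234840 CPM ± 43027 (SD, n = 6) against 48955 to 75768 CPM in the mtDNA strains, a log2 fold change of 1.92 ± 0.10 (SE, adjusted p = 1.85e-19). Actn3, the alpha-actinin of fast fibres, stood at 7.13 CPM ± 0.916 against 230.2 to 336.5 CPM, a log2 fold change of -5.27 ± 0.56 (adjusted p = 1.12e-10). Of 13935 genes tested, 3120 rose and 3533 fell, 6653 in all (7476 at an unadjusted p under 0.05, and 6651 called by DESeq2).

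All 13 mtDNA-encoded mRNAs rose (median log2 fold change 1.64, list adjusted p = 5.35e-21). mt-Nd1 rose by 1.88 ± 0.10 on the log2 scale, mt-Nd5 by 1.54 ± 0.12 and mt-Nd6 by 1.51 ± 0.09. The nuclear subunits of the respiratory chain moved with them. All 36 tested subunits of complex I rose (median 0.83, adjusted p = 1.58e-36), among them Ndufs8 (1.14 ± 0.07) and Ndufa11 (1.01 ± 0.06). All 9 of complex III rose (median 0.72, adjusted p = 4.19e-12), with Cyc1, the cytochrome c1 gene, at 0.85 ± 0.06. All 14 of complex IV (median 0.79, adjusted p = 2.35e-17) and all 15 of ATP synthase (median 0.75, adjusted p = 1.16e-17) rose as well, with Cox4i1 at 0.90 ± 0.06 and Atp5g1, a gene of the membrane ring of ATP synthase, at 1.15 ± 0.07. Of 76 genes of the mitochondrial ribosome, 73 rose (median 0.52, adjusted p = 2.19e-40), including Mrpl3 (0.94 ± 0.07). These 6 lists were the only ones of the 37 tested in this comparison whose call held with an estimated correlation, with adjusted p = 0.0324 for the ribosome and 0.0451 for the other 5. These lists held in the same way against ND6 and against CO1 alone, and against ND5 alone none of 26 list calls did (adjusted p = 0.0553 for each of the 6). Adjusted over the list alone, the counts of these 6 lists were the same as over all genes.

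Fuel oxidation rose too. All 17 genes of the tricarboxylic acid cycle (median 0.63, adjusted p = 1.56e-13, and adjusted p = 0.124 with an estimated correlation) and 18 of 19 genes of fatty acid oxidation (median 0.69, adjusted p = 1.49e-13, and adjusted p = 0.138 with an estimated correlation) were higher. Eci1 and Hadh, enzymes of fatty acid breakdown, rose by 1.25 ± 0.11 and 1.04 ± 0.08. Of 13 mitochondrial chaperones and proteases 12 rose (median 0.44, adjusted p = 6.7e-07, and adjusted p = 0.124 with an estimated correlation). The 3 genes with the smallest p among those that rose were S100a1, a calcium-binding protein of striated muscle (1.78 ± 0.08, adjusted p = 7.25e-22), Pdhb, a subunit of pyruvate dehydrogenase (0.94 ± 0.05), and the mitochondrial peroxiredoxin Prdx5 (1.19 ± 0.06). Nnt, the proton-driven transhydrogenase of the inner membrane, did not pass the test (0.23 ± 0.20, adjusted p = 0.349). Among 7 carriers of adenine nucleotides and phosphate, 3 rose and 3 fell. Slc25a5, which encodes the translocator isoform ANT2, rose by 0.99 ± 0.11, the phosphate carrier Slc25a3 rose by 0.80 ± 0.06, and the ATP-Mg carrier Slc25a23 had a log2 fold change of -0.48 ± 0.09 (adjusted p = 3.15e-05). For this list the median (0.41) and the preset test pointed up and the mean (-0.91) pointed down, with an adjusted p of 0.995. In all, 4 lists of this comparison differed in sign in this way, none of them past the threshold.

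Contractile and stress genes changed within lists that did not pass as a whole. Of 14 fast-fibre genes, 3 rose and 7 fell (5 and 7 adjusted over the list alone, median -0.83, adjusted p = 0.107). Actn3 and the calcium buffer Pvalb (-4.71 ± 0.68) fell. The fast myosin gene Myh4, chosen after its values were seen, lay at 3.67 to 5.04 on the log2 CPM scale in ANT1. It spread from 4.64 to 11.1 in ND5 and from 5.82 to 10.6 in CO1. Fast muscle taken with the soleus is therefore not excluded for these falls. Of 11 slow-fibre genes, 1 rose and 5 fell (the same adjusted over the list alone, median -0.28, adjusted p = 0.131). The slow troponin I gene Tnni1 fell by 1.51 on the log2 scale and the ventricular and slow light chain Myl3 rose by 0.74 ± 0.11. Mettl21c, which encodes a muscle protein methyltransferase, had the smallest p after Slc25a4 among genes that fell (-5.84 ± 0.33, adjusted p = 9.13e-19), at 1.30 CPM against 68.1 to 80.9 CPM. Myoz3, a Z-disc protein of fast fibres (-3.58 ± 0.25), Ablim1 (-2.85 ± 0.17), the SERCA inhibitor Sln (-4.36 ± 0.44) and Mstn, the gene of the growth inhibitor myostatin (-2.64 ± 0.58), fell as well. The list of atrophy and denervation genes fell (2 rose and 10 fell of 17, over the list alone too, median -0.91, adjusted p = 0.0321, and adjusted p = 0.38 with an estimated correlation), a call lost without ANT1 mouse A82 (median -0.88, adjusted p = 0.052). Of 24 genes of the integrated stress response 8 rose and 2 fell, also over the list alone, without a shift of the list (median 0.01, adjusted p = 0.239). Gdf15, a hormone released under mitochondrial stress, rose by 1.94 ± 0.30 on the log2 scale, and Nupr1 rose 2.82-fold (adjusted p = 4.93e-16).

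Matrix and macrophage transcripts were lower in ANT1 soleus. All 25 extracellular matrix genes fell (median -1.60, adjusted p = 1.42e-07, and adjusted p = 0.38 with an estimated correlation), among them Col1a1 (-2.54 ± 0.51), fibronectin Fn1 (-2.44 ± 0.39) and periostin Postn (-3.46 ± 0.67). All 7 tendon markers fell (median -1.61, adjusted p = 0.00649, and adjusted p = 0.376 with an estimated correlation), and 7 of 10 macrophage markers fell (median -0.99, adjusted p = 0.00974, and adjusted p = 0.38 with an estimated correlation), with Adgre1, the F4/80 antigen, at -1.64 ± 0.36. Adjusted over the list alone the counts were 25, 7 and 7. All 6 red blood cell markers rose (median 0.85, adjusted p = 0.00974, and adjusted p = 0.38 with an estimated correlation). These groups moved with the choice of reference strain. Against ND5, ND6 and CO1 in turn, 25, 6 and 19 matrix genes and 10, 0 and 6 macrophage markers fell.

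Against each mtDNA strain separately, ANT1 soleus differed in 6835 (ND5), 4297 (ND6) and 4905 (CO1) genes, and 3314 genes were called in the same direction against all 3 (1802 higher and 1512 lower). The 3 comparisons share the ANT1 libraries. Independent lists of these sizes would share 186 genes, and with 2 separate ANT1 libraries for each comparison 1313 genes were shared (916 higher and 397 lower).

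**Figure D2:**
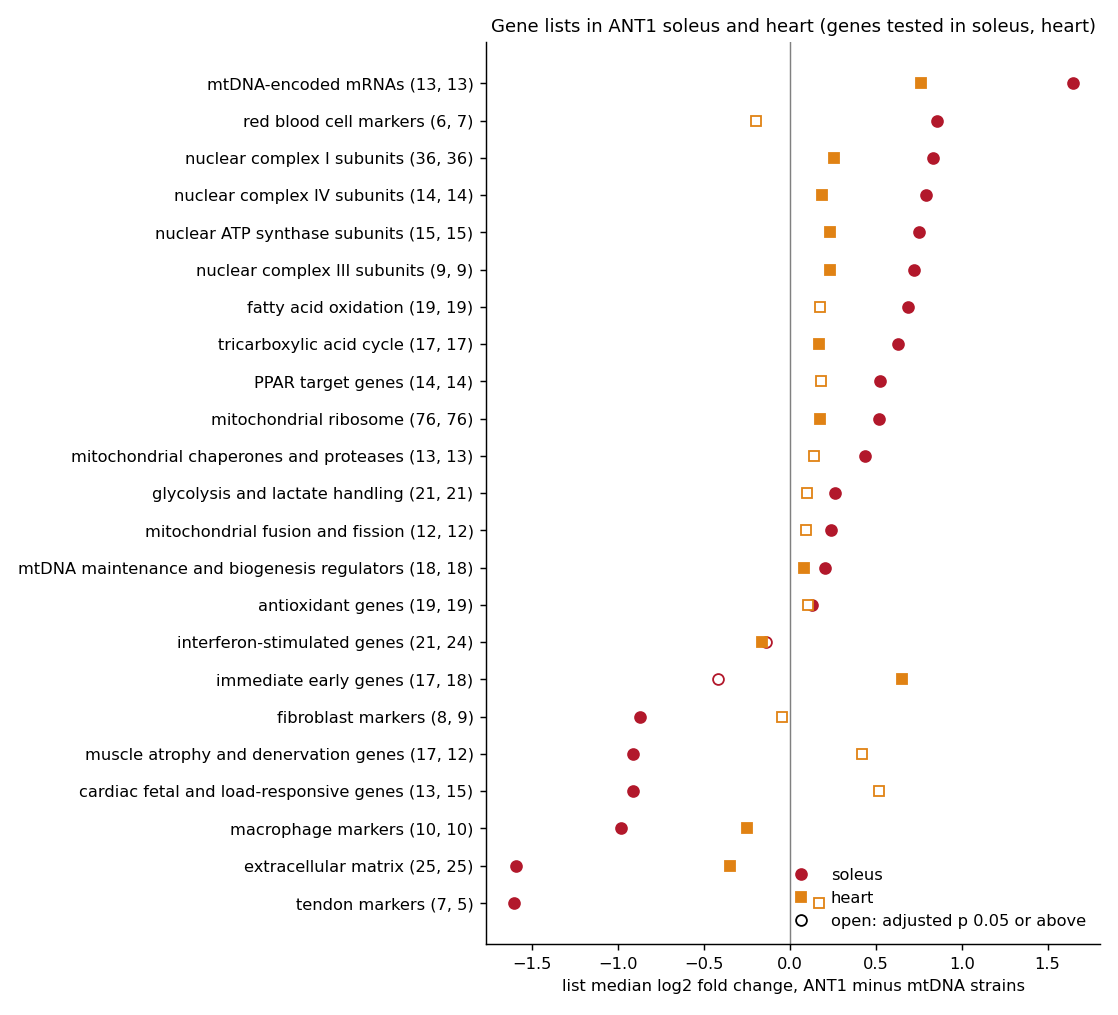
Median log2 fold change of the 23 gene lists past the threshold in soleus (circles) or heart (squares) for ANT1 minus the mean of the mtDNA strains in non-exercised mice, with filled symbols where the list's adjusted p was under 0.05. The list of mtDNA-encoded mRNAs lies at 1.64 in soleus and 0.76 in heart, and the extracellular matrix list at -1.60 and -0.35.

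In heart, the loss of Slc25a4 (-9.51 ± 0.38, adjusted p = 8.3e-23) went with far fewer differences. The mtDNA-encoded mRNAs rose as a list (median log2 fold change 0.76, adjusted p = 4.6e-14, and adjusted p = 0.741 with an estimated correlation), and 4 of the 13 were called (13 adjusted over the list alone), among them mt-Nd3 (1.05 ± 0.22, adjusted p = 0.00506) and mt-Nd2 (0.99 ± 0.24, adjusted p = 0.0218). mt-Co1 (0.66 ± 0.26, adjusted p = 0.281), mt-Nd5 (0.60 ± 0.25, adjusted p = 0.309), mt-Nd6 (0.57 ± 0.23, adjusted p = 0.319) and Nnt (0.24 ± 0.37, adjusted p = 0.845) did not pass. Of 15723 genes, 97 rose and 47 fell, 144 in all (1820 at an unadjusted p under 0.05, and 211 called by DESeq2). Of 100 splits of the heart libraries into groups of these sizes, 13 gave at least 144 genes and the highest other 2361. Without single ANT1 libraries the count was 68 (A72), 69 (A23) and 242 (A80). mt-Nd2 was not called without A58, A72, A23 or A70 (adjusted p = 0.056 to 0.105).

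Among the genes with the smallest p in heart, Arrdc4, an arrestin-like regulator of glucose uptake, rose by 1.08 ± 0.10 (adjusted p = 1.04e-09), the RNase H2 subunit Rnaseh2a by 0.60 ± 0.08, the iron carrier of mitochondria Slc25a28 by 0.70 ± 0.10 and the splicing helicase Ddx23 by 0.41 ± 0.05. Il15, a cytokine made by muscle, had a log2 fold change of -3.11 ± 0.38 (adjusted p = 4.78e-07). Leprotl1 (-0.65 ± 0.07), glutathione reductase Gsr (-0.72 ± 0.10), Scoc (-0.40 ± 0.06), the oxygen sensor Egln3 (-2.46 ± 0.38), Rnf150 (-1.04 ± 0.17) and the chaperone calreticulin Calr (-0.47 ± 0.08) fell too. Gdf15 rose by 2.34 ± 0.55 (adjusted p = 0.0172), and without mouse A72 stood at 0.96 (adjusted p = 0.662), without A23 at 2.27 (adjusted p = 0.0635). Il15, Gsr, Leprotl1, Calr, Scoc, Rnf150, Rnaseh2a and Gdf15 lie within 50 Mb of Slc25a4 on chromosome 8. Slc25a5 did not pass (0.27 ± 0.13, adjusted p = 0.414).

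Nuclear mitochondrial lists were higher in ANT1 heart by the preset test, with smaller medians than in soleus. Complex I stood at a median of 0.26 (adjusted p = 2.87e-07) and the mitochondrial ribosome at 0.17 (adjusted p = 6.71e-09), with 0 of 36 and 0 of 76 genes called, over the list alone too, and adjusted p = 0.741 for both with an estimated correlation. The matrix list was lower (median -0.35, adjusted p = 7.09e-05, 0 of 25 called, over the list alone too, and adjusted p = 0.741 with an estimated correlation). The atrial list stood at a median of 1.79 (adjusted p = 0.0211, 0 of 8 called, over the list alone too, and adjusted p = 0.793 with an estimated correlation) and the brown adipocyte list at -2.56 (adjusted p = 0.0473, 0 of 6 called, over the list alone too, and adjusted p = 0.741 with an estimated correlation). None of the 15 list calls in this comparison held with an estimated correlation. Without mouse B80 the matrix median was -0.15. The atrial call was lost without A63 or A80 (medians 1.27 and 0.93), and the brown adipocyte call without any of 15 single libraries, with B80 moving its median furthest (-1.41). The atrial light chain Myl7 stood at 542.1 CPM ± 786 (SD, n = 6) in ANT1, 640.8 CPM ± 753 in ND5, 714.7 CPM ± 1044 in ND6 and 6.401 CPM ± 12.4 in CO1, and its strain difference did not pass (1.92 ± 1.28, adjusted p = 0.588). Exercised mice gave 751 genes, both arms together 1977, and a fit with the atrial score as a covariate 1063.

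Against each mtDNA strain, 736, 38 and 65 heart genes were called for ND5, ND6 and CO1, and 28 were called in the same direction against all 3 (13 higher and 15 lower). Independent lists would share 0.00187, and separate ANT1 libraries shared 8 (5 higher and 3 lower). Over 13555 genes tested in both tissues, ANT1 effects in soleus and heart had a Pearson r of 0.366 and a Spearman rho of 0.418 across genes, which are not independent replicates. Of these genes 56 rose in both tissues, where independent lists would share 18.02, and 35 fell in both, where they would share 11.04. Il15 was the 1 gene that rose in soleus and fell in heart, and 3 genes fell in soleus and rose in heart. With the atrial score as a covariate in heart, 507 genes rose in both (160.8 expected) and 180 fell in both (67.5 expected), 5 rose in soleus and fell in heart, and 25 fell in soleus and rose in heart.

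**Figure D3:**
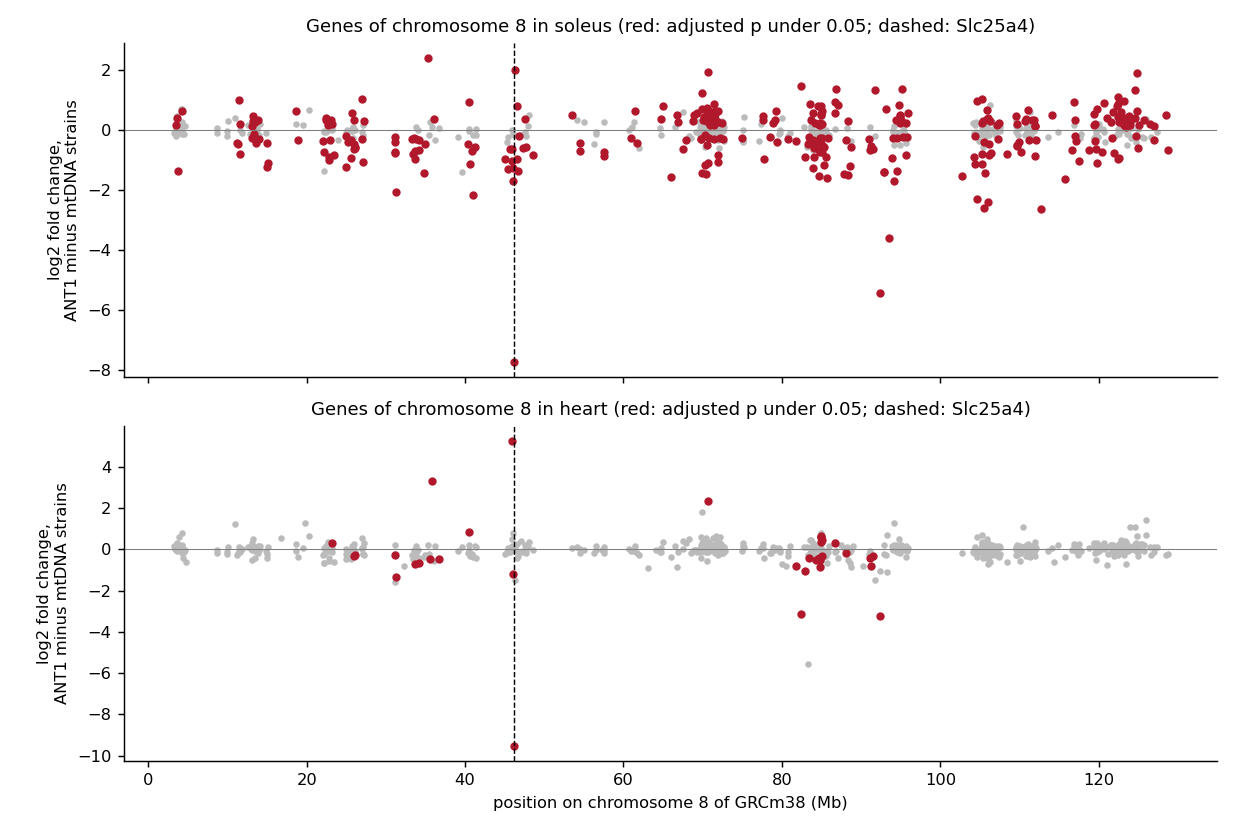
Log2 fold change of genes along chromosome 8 (position in Mb, mm10) for ANT1 minus the mean of the mtDNA strains in soleus and heart, with called genes in red and Slc25a4 marked by the dashed line. The 35 called heart genes near Slc25a4 lie between 23226616 and 92356120.

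The tissue difference itself was tested for ANT1. The rise of mitochondrial transcripts was larger in soleus than in heart, by 1.30 ± 0.29 on the log2 scale for mt-Co1 (adjusted p = 0.00107), 0.97 ± 0.29 for mt-Nd5, 0.98 ± 0.27 for mt-Nd6 and 0.89 ± 0.18 for Ndufs8. Of 16172 genes, 894 had a higher and 903 a lower ANT1 effect in soleus, 1797 in all (4072 at an unadjusted p under 0.05, 1889 by DESeq2, and 1237 with the mouse as a block in limma voom). The mtDNA-encoded list (11 of 13 genes, 13 adjusted over the list alone, median 0.97, adjusted p = 2.52e-10), complex I (22 of 36, 32 adjusted over the list alone, median 0.61, adjusted p = 1.59e-17) and the matrix list (14 of 25 lower, 19 adjusted over the list alone, median -1.28, adjusted p = 3.6e-10) differed between tissues, with adjusted p = 0.365 for each with an estimated correlation. Kcnk3, a background potassium channel, differed by 4.87 on the log2 scale (SE 0.32, adjusted p = 7.19e-22). It stood at 6.69 CPM ± 2.53 in ANT1 soleus and 0.20 to 0.27 CPM in the other soleus groups, and at 167 to 186 CPM in the hearts of all strains. Il15 (4.62 ± 0.39) stood at 8.52 CPM in ANT1 soleus against 2.55 to 3.45 CPM, and at 1.98 CPM in ANT1 heart against 12.6 to 20.9 CPM. N4bp1 differed by 1.52 ± 0.12. Both Il15 and N4bp1 lie within 50 Mb of Slc25a4. The receptor gene Eda2r (-2.55 ± 0.28), Ablim1 (-2.80 ± 0.32), the load-responsive Ankrd1 (-3.50 ± 0.68) and Col1a1 (-2.21 ± 0.53) differed in the other direction. Slc25a4 differed by 1.82 ± 0.27, and Nnt by 0.02 ± 0.43 (adjusted p = 0.998).

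Between the mtDNA strains, ND5 soleus stood apart from ND6 soleus in higher matrix, macrophage and embryonic muscle transcripts and lower mtDNA-encoded transcripts. Tenascin C, Tnc, a matrix protein of injured and growing muscle, stood at 56.4 CPM ± 55.5 (SD, n = 6) in ND5, 2.52 CPM ± 1.74 in ND6 and 7.55 CPM ± 10.05 in CO1, and was 22.7-fold higher in ND5 than in ND6 (adjusted p = 0.00261). Embryonic myosin Myh3 was higher by 3.53 ± 0.91 on the log2 scale (adjusted p = 0.00871) and perinatal myosin Myh8 by 3.96 ± 0.83 (adjusted p = 0.00347). Of 13935 genes 1389 were higher and 628 lower in ND5, 2017 in all (4242 at an unadjusted p under 0.05, and 2380 by DESeq2). In ND5 the SD of Tnc was nearly as large as its mean. Without single libraries the count was 442 (B70), 880 (B85), 1305 (B19), 1243 (I18) and 3293 (B10).

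Of 25 matrix genes, 24 were higher in ND5 (25 adjusted over the list alone, median 1.56, adjusted p = 2.91e-18, and adjusted p = 0.317 with an estimated correlation). They included Col1a1 (2.63 ± 0.54), the cross-linking enzyme Lox (2.48 ± 0.48), the protease inhibitor Timp1 (3.10 ± 0.65) and Col5a3 (1.77 ± 0.31). Of 10 macrophage markers, 8 were higher (10 adjusted over the list alone, median 1.36, adjusted p = 3.64e-08, and adjusted p = 0.317 with an estimated correlation), with the complement gene C1qb at 1.51 ± 0.30 and Adgre1 at 1.64 ± 0.35. Of 17 atrophy and denervation genes, 8 were higher and 2 lower (9 and 2 adjusted over the list alone, median 0.68, adjusted p = 0.0119, and adjusted p = 0.317 with an estimated correlation). The fetal acetylcholine receptor subunit Chrng (2.86 ± 0.68) and the muscle differentiation factor Myog (2.07 ± 0.45) were among the higher ones. Adam12 (2.93 ± 0.55), Serpinb1a (2.40 ± 0.42) and the microtubule regulator Stmn1 (1.92 ± 0.33) were higher as well. Of 7 tendon markers 2 were higher, over the list alone too (median 0.42, adjusted p = 0.158), and 0 of 14 fast-fibre genes were called, over the list alone too (median -0.19, adjusted p = 0.503).

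Mitochondrial transcripts were lower in ND5 than in ND6 soleus. Of 13 mtDNA-encoded mRNAs 9 were lower (10 adjusted over the list alone, median -0.59, adjusted p = 4.99e-10, and adjusted p = 0.317 with an estimated correlation), with mt-Nd5, the gene mutated in ND5 mice, at -0.81 ± 0.16, mt-Nd2 at -0.68 ± 0.14, mt-Nd6 at -0.65 ± 0.12 and mt-Co1 at -0.63 ± 0.14. Fatty acid oxidation (14 of 19 lower, 17 adjusted over the list alone, median -0.36, adjusted p = 5.55e-10), the tricarboxylic acid cycle (10 of 17 lower, 14 adjusted over the list alone, median -0.26, adjusted p = 2.46e-08) and complex I (10 of 36 lower, 14 adjusted over the list alone, median -0.18, adjusted p = 1.41e-08) fell with them, with adjusted p = 0.317 for each with an estimated correlation. Ppargc1a, a coactivator of mitochondrial biogenesis, fell by 1.30 on the log2 scale (SE 0.41), Acadm by 0.46 (SE 0.11) and Idh3b by 0.37 (SE 0.09). Ppargc1a was not called without I13, I100, B70, B19 or B85 (adjusted p = 0.0571 to 0.0945), nor Idh3b without B70 (adjusted p = 0.0505). The scavenger receptor Stab2 (-1.31 ± 0.23), Myh13 (-1.09 ± 0.20) and the squalene synthase Fdft1 (-0.70 ± 0.15) were lower too. Nnt (-0.55 ± 0.24, adjusted p = 0.117) and Slc25a4 (-0.30 ± 0.15, adjusted p = 0.157) did not pass. Exercised mice gave 0 genes for this comparison, with Col1a1 at -0.12 and Myh3 at -1.32 on the log2 scale, and both arms together gave 557. Without exercised ND6 mouse I59, exercised mice again gave 0 genes with edgeR, with Col1a1 at 0.54 and Myh3 at 0.38.

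ND5 against CO1 soleus gave 0 genes with edgeR (3080 at an unadjusted p under 0.05, and 410 by DESeq2). Timp1 stood at 2.37 ± 0.62 (adjusted p = 0.0634), Lox at 1.71 ± 0.46 (adjusted p = 0.0634), C1qb at 1.01 ± 0.29 (adjusted p = 0.0653), mt-Nd5 at -0.46 ± 0.16 (adjusted p = 0.0912) and mt-Co1 at -0.40 ± 0.14 (adjusted p = 0.0954). Adjusted over the list alone, 23 of 25 matrix genes were higher (median 1.12, adjusted p = 1.43e-13, and adjusted p = 0.517 with an estimated correlation). ND6 against CO1 gave 0 genes with edgeR (286 at an unadjusted p under 0.05, and 1 by DESeq2), with Col1a1 at -1.07 ± 0.52, mt-Co1 at 0.23 ± 0.14 and mt-Nd6 at 0.35 ± 0.12 (adjusted p = 0.9997 for each), and the matrix list at a median of -0.61 (0 of 25 called, over the list alone too, adjusted p = 1.01e-09, and adjusted p = 0.628 with an estimated correlation). Both arms together gave 646 genes for ND5 against CO1, and without ANT1 libraries A81 and A82 the non-exercised mice gave 10. Without single libraries ND5 against CO1 gave 219 (B3), 1685 (B10), 520 (B47), 1 (E42), 744 (E64) and 445 (E98), and the matrix median of ND6 against CO1 was -0.29 without E64.

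**Figure D4:**
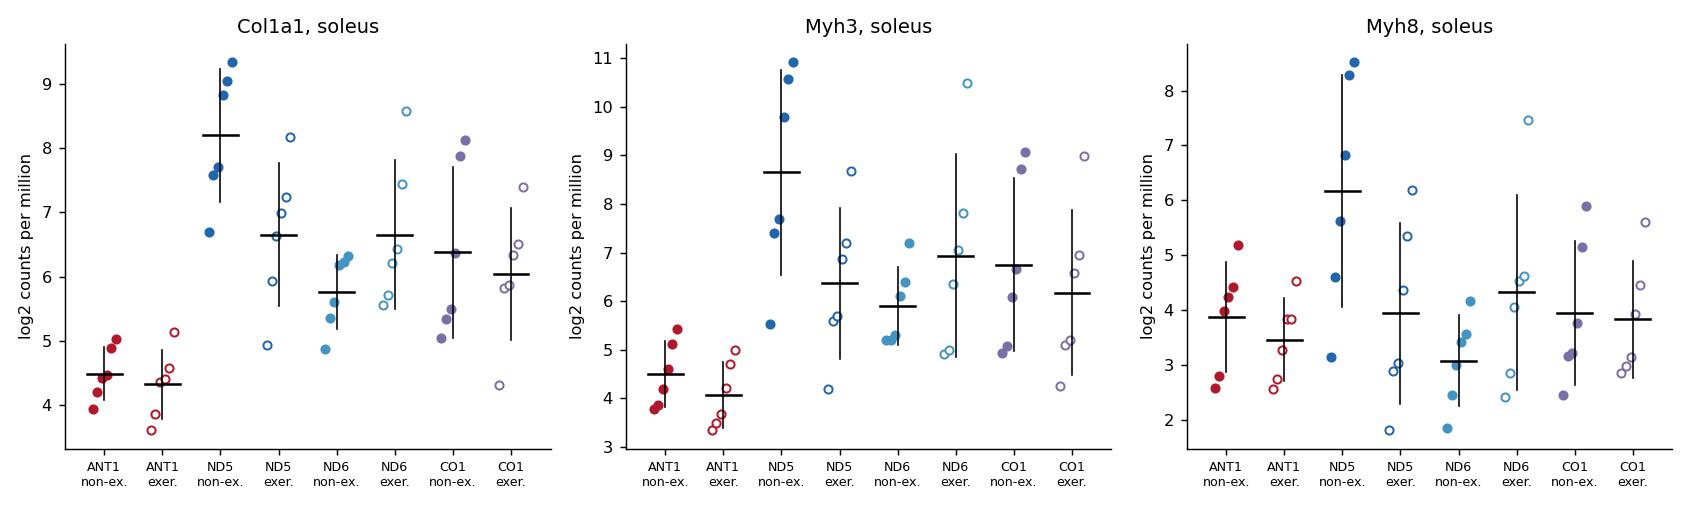
Log2 CPM of Col1a1, Myh3 and Myh8 in each soleus library by strain, filled for non-exercised and open for exercised mice, with bars at the mean and whiskers of 1 SD (n = 6). Non-exercised ND5 mice average 8.65 ± 2.11 (SD) for Myh3 and ND6 mice 5.90 ± 0.81.

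In heart, ND5 mice differed from CO1 mice in matrix genes and in markers of cells other than ventricular muscle. Grip2, a scaffold protein, was higher in ND5 by 1.65 ± 0.24 (adjusted p = 0.000438), and the endoplasmic reticulum chaperones Hyou1 (0.83 ± 0.14), Pdia3 (0.73 ± 0.13) and Pdia4 (1.13 ± 0.22) and the secreted factor Manf (1.18 ± 0.20) were higher as well. Of 15723 genes, 1458 were higher and 302 lower in ND5, 1760 in all (5193 at an unadjusted p under 0.05, and 2433 by DESeq2). Without ND5 mouse B80 5 genes were called, in a fit on the compared groups only 0, and in exercised mice 0. Without other single libraries the count was 3016 (B70), 3247 (B5), 726 (B10), 897 (E64), 719 (E55), 548 (E69) and 903 (E53).

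Of 25 matrix genes 22 were higher, over the list alone too (median 1.29, adjusted p = 4.44e-14, and adjusted p = 0.363 with an estimated correlation), with Col1a1 at 1.79 ± 0.35 and Col3a1 at 2.03 ± 0.41. Of 25 genes of the integrated stress response 8 were higher (10 higher and 3 lower adjusted over the list alone, median 0.33, adjusted p = 0.032, and adjusted p = 0.37 with an estimated correlation), with the stress-induced Nupr1 5.67-fold higher (adjusted p = 0.0135). Of 76 genes of the mitochondrial ribosome 2 were lower (0 adjusted over the list alone, median -0.35, adjusted p = 3.35e-14, and adjusted p = 0.363 with an estimated correlation). Without B80 the matrix median was 0.81 and that of the stress response 0.26 (adjusted p = 0.114), and Pdia4, Col1a1, Col3a1 and Nupr1 were not called (adjusted p = 0.125, 0.16, 0.16 and 0.341). The stress response call was also lost without B81, E42 or E75. Pdk4, an inhibitor of pyruvate oxidation, was lower (-2.21 ± 0.72, adjusted p = 0.0406), as was Herc1 (-0.58 ± 0.09). The call of Pdk4 was lost without B80 (adjusted p = 0.196), and without B81, B10, B21, E64, E55, E69 or E53 (adjusted p = 0.0565 to 0.0904). Slc25a4 (-0.49 ± 0.27, adjusted p = 0.19), mt-Co1 (-0.64 ± 0.33, adjusted p = 0.165), mt-Nd5 (-0.38 ± 0.31, adjusted p = 0.386), mt-Nd6 (-0.44 ± 0.30, adjusted p = 0.283) and Nnt (-0.58 ± 0.45, adjusted p = 0.359) did not pass.

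Markers of other cell types moved with these groups. Of 8 atrial markers 3 were higher in ND5 (7 adjusted over the list alone, median 5.69, adjusted p = 0.00127, and adjusted p = 0.37 with an estimated correlation), with Myl7 at 6.65 ± 2.18 and Fgf12 at 6.34 ± 2.00. Of 10 adipocyte markers 6 were higher (7 adjusted over the list alone, median 6.92, adjusted p = 0.000267, and adjusted p = 0.37 with an estimated correlation), with the fat hormone gene Adipoq at 7.63 ± 1.86 and the lipid droplet coat Plin1 at 8.37 ± 2.05. Of 6 brown adipocyte markers 4 were higher, over the list alone too (median 5.47, adjusted p = 0.0188, and adjusted p = 0.686 with an estimated correlation). Of 7 red blood cell markers 1 was higher (7 adjusted over the list alone, median 2.76, adjusted p = 0.00195, and adjusted p = 0.37 with an estimated correlation), with the anion exchanger Slc4a1 at 3.41 ± 1.12. Of 8 smooth muscle and pericyte markers 5 were higher, over the list alone too, with Acta2 at 4.43 ± 1.03 (list median 2.81, adjusted p = 0.0768). Adipoq stood at 49.5 CPM ± 102 (SD, n = 6) in ND5 and 0.250 CPM ± 0.258 in CO1 hearts. In the heart of mouse B80 it reached 8.05 on the log2 CPM scale. Without B80 the medians were 4.48 for adipocyte markers (adjusted p = 0.0192), 1.22 for brown adipocyte markers (adjusted p = 0.571), 1.197 for red blood cell markers (adjusted p = 0.0636) and 0.61 for smooth muscle markers. Myl7, Fgf12, Adipoq, Plin1, Acta2 and Slc4a1 were not called without it (adjusted p = 0.185 to 0.489). The calls of Myl7 and Fgf12 were also lost without B81, B10, E64, E55, E69, E75 or E53 (adjusted p = 0.0562 to 0.091), and that of Slc4a1 without B10, E42, E64, E55, E69 or E53 (adjusted p = 0.0562 to 0.092).

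ND5 against ND6 hearts gave 0 genes with edgeR (1025 at an unadjusted p under 0.05, and 1 by DESeq2), with Eln, the elastin gene, at 1.73 ± 0.60 (adjusted p = 0.659), mt-Nd5 at -0.35 ± 0.31 and mt-Nd6 at -0.49 ± 0.30 (adjusted p = 0.876 and 0.82). The matrix list had a median of 0.57 (10 of 25 higher adjusted over the list alone and 0 over all genes, adjusted p = 1.46e-13, and adjusted p = 0.554 with an estimated correlation), which fell to 0.0950 without mouse B80 (adjusted p = 0.0502). ND6 against CO1 hearts gave 0 genes with edgeR (2164 at an unadjusted p under 0.05, and 96 by DESeq2), with Myl7 at 6.81 ± 2.20 (adjusted p = 0.253) and Fgf12 at 6.38 ± 2.00 (adjusted p = 0.247). mt-Co1 at -0.19 ± 0.33 (adjusted p = 0.791) and mt-Nd6 at 0.04 ± 0.30 (adjusted p = 0.952) did not pass. All 8 atrial markers were higher adjusted over the list alone (0 over all genes, median 5.93, adjusted p = 2.86e-06, and adjusted p = 0.595 with an estimated correlation). Exercised mice gave 89 genes for ND6 against CO1, and both arms together 2681. Without single libraries the count was 6 (E64) and 27 (E75).

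**Figure D5:**
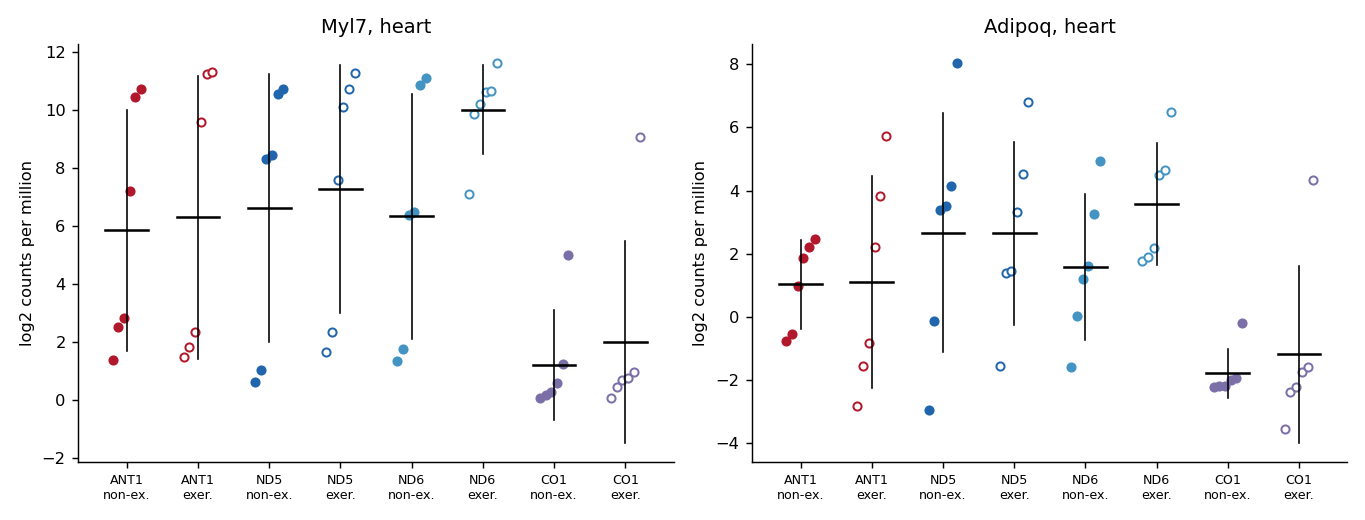
Log2 CPM of the atrial light chain Myl7 and of Adipoq in each heart library by strain, filled for non-exercised and open for exercised mice, with bars at the mean and whiskers of 1 SD (n = 6). Myl7 spans 0.09 to 11.6 over the hearts, and non-exercised CO1 mice average 1.23 ± 1.90.

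The mtDNA strains were also compared between tissues. The ND5 against ND6 difference in soleus exceeded that in heart for the proliferation genes Stmn1 (1.91 ± 0.37, adjusted p = 0.0131) and Mki67 (3.03 ± 0.66, adjusted p = 0.0274) and for Col5a3 (1.97 ± 0.39), and Bmpr1b lay the other way (-4.03 ± 0.89). In all 20 genes were higher and 4 lower, 24 together (120 by DESeq2). For ND5 against CO1, 9 genes were higher and 144 lower, 153 together, with Stmn1 at 1.64 ± 0.36, carbonic anhydrase 3, Car3, at -7.82 ± 1.66, Adipoq at -8.00 ± 1.74 and Bmpr1b at -5.50 (adjusted p = 0.00599). With the mouse as a block in limma voom 0 genes were called for ND5 against CO1, and without mouse B80 0 in edgeR. For ND6 against CO1 1 gene was called, the unnamed clone RP24-200D3.4 (2.11 ± 0.41, adjusted p = 0.0315), which was chosen after its values were seen, and with the mouse as a block it was 0.

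Training was examined within each strain, 6 exercised against 6 non-exercised mice. In soleus no gene passed in any strain with edgeR. ND5 mice had the largest shift at unadjusted p (2086 genes, against 350 in ANT1, 688 in ND6 and 268 in CO1). In exercised ND5 soleus the matrix list was lower (median -0.84, 19 of 25 adjusted over the list alone and 0 over all genes, adjusted p = 6.99e-13, and adjusted p = 0.318 with an estimated correlation), with Col1a1 at -1.50 ± 0.52 and Lox at -1.42 ± 0.46 (adjusted p = 0.171 and 0.154). mtDNA-encoded mRNAs (median 0.35, 6 of 13 adjusted over the list alone and 0 over all genes, adjusted p = 3.33e-07) and complex I (median 0.16, 0 of 36 in either count, adjusted p = 3.22e-12) were higher, with adjusted p = 0.318 for both with an estimated correlation. mt-Co1 stood at 0.39 ± 0.14 (adjusted p = 0.182), mt-Nd5 at 0.39 ± 0.16 (adjusted p = 0.215) and Acadm, a dehydrogenase of fatty acid oxidation, at 0.33 ± 0.11 (adjusted p = 0.171). DESeq2 called 51 genes in ND5, 1 in ANT1, 2 in ND6 and 0 in CO1. Without single ND5 libraries edgeR called 44 higher and 136 lower (B9), 149 and 272 (B10), and 14 and 52 (B47).

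The other strains were examined in the same way in soleus, and no test compared the lists between strains. In ND6 the matrix list was higher (median 0.73, 0 of 25 in either count, adjusted p = 4.41e-12, and adjusted p = 0.524 with an estimated correlation), with Col1a1 at 1.25 ± 0.52, Myh3 at 2.26 ± 0.86 and Myh8 at 2.18 ± 0.79 (adjusted p = 0.954 for each). Without exercised mouse I59 these were 0.36 for the list median, 0.59, 0.55 and 0.70. mt-Co1 stood at -0.01 ± 0.14 and mt-Nd6 at 0.01 ± 0.12 in ND6. In ANT1 the slow-fibre list was higher (median 0.22, 0 of 11 in either count, adjusted p = 5.87e-07, and adjusted p = 0.53 with an estimated correlation), with slow troponin T Tnnt1 at 0.24 ± 0.10, the adipokine Retn at 1.09 ± 0.39 and mt-Co1 at -0.10 ± 0.14. In CO1 complex I was higher (median 0.11, 0 of 36 in either count, adjusted p = 3.72e-15, and adjusted p = 0.413 with an estimated correlation), with Ndufa9 at 0.15 ± 0.08, the adipocyte gene Cfd at 0.87 ± 0.38 (0.26 without E50) and mt-Co1 at 0.18 ± 0.14, and the median was 0.0591 without E1. Averaged over strains, 0 genes passed (536 at an unadjusted p under 0.05, and 0 by DESeq2), with complex I at a median of 0.07 (0 of 36 in either count, adjusted p = 1.01e-14, and adjusted p = 0.472 with an estimated correlation), Cfd at 0.57 ± 0.19, Ndufa9 at 0.10 ± 0.04 and mt-Co1 at 0.11 ± 0.07. The test for a training effect that differs between strains gave 0 genes (984 at an unadjusted p under 0.05, and 0 by DESeq2).

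In heart 0 genes passed for training in any strain with edgeR (353 in ANT1, 793 in ND5, 680 in ND6 and 287 in CO1 at an unadjusted p under 0.05, and 1, 1, 0 and 1 by DESeq2). In ND5 the matrix list was lower (median -0.73, 20 of 25 adjusted over the list alone and 0 over all genes, adjusted p = 5.51e-28, and adjusted p = 0.161 with an estimated correlation), with Postn at -2.06 ± 0.60 (adjusted p = 0.399), Acta2 at -3.36 ± 0.98 (adjusted p = 0.405) and mt-Nd5 at 0.05 ± 0.31. Without mouse B80 the matrix median was -0.25 (adjusted p = 2.76e-08), and without B9, B83, B13 or B71 edgeR called 1 gene. In ND6 fatty acid oxidation was lower (median -0.43, 0 of 19 in either count, adjusted p = 1.2e-07, and adjusted p = 0.493 with an estimated correlation), with Acadl at -0.40 ± 0.22 and mt-Nd6 at -0.36 ± 0.30. In CO1 the atrial list was higher (median 3.34, 0 of 8 in either count, adjusted p = 1.07e-06, and adjusted p = 0.894 with an estimated correlation), with Myl7 at 3.81 ± 1.92 and mt-Co1 at -0.08 ± 0.33. Without exercised mouse E50 the atrial median was -1.94 (adjusted p = 0.00455) and Myl7 stood at -2.14, and without E42 the median was 5.42. In ANT1 the brown adipocyte list was higher (median 2.82, 0 of 6 in either count, adjusted p = 0.00198, and adjusted p = 0.971 with an estimated correlation) and mt-Co1 stood at -0.13 ± 0.33. Without mouse A17 that median was 1.19 (adjusted p = 0.137). On average over strains 0 genes passed (538 at an unadjusted p under 0.05, and 1 by DESeq2), with Myl7 at 1.53 ± 0.87, mt-Co1 at -0.12 ± 0.16 and fatty acid oxidation at a median of -0.14 (0 of 19 in either count, adjusted p = 0.000213, and adjusted p = 0.91 with an estimated correlation). The test for a difference between strains gave 0 genes (644 at an unadjusted p under 0.05, and 1 by DESeq2).

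The labels class exercised soleus samples as responders or non-responders to training, 3 of each per strain. Averaged over strains, 0 genes passed with edgeR (622 at an unadjusted p under 0.05, and 0 by DESeq2). The fast-fibre list was lower in responders (median -0.17, 0 of 14 in either count, adjusted p = 2.55e-05, and adjusted p = 0.687 with an estimated correlation), with Pvalb at -1.23 ± 0.44 and Actn3 at -0.80 ± 0.39 (adjusted p = 0.954 for both). Without ANT1 mouse A30 these were -0.74 and -0.46, and without ND5 mouse B98 Actn3 stood at -0.46. Heat shock chaperones (median 0.17, 0 of 13 in either count, adjusted p = 1.45e-05, and adjusted p = 0.687 with an estimated correlation) and the mitochondrial ribosome (median 0.05, 0 of 76 in either count, adjusted p = 3.97e-09, and adjusted p = 0.69 with an estimated correlation) were higher, with the chaperone Hsph1 at 0.28 ± 0.12. Without ND5 mouse B69 the chaperone median was 0.0995 (adjusted p = 0.00178). Slc25a4 stood at -0.11 ± 0.10 and mt-Co1 at 0.09 ± 0.11. Without single mice Slc25a4 moved to -0.05 (A13) and -0.21 (A43), and mt-Co1 to 0.02 (A81), 0.04 (I59) and 0.14 (I84).

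Within strains, 0 genes passed in each with edgeR (594 in ANT1, 1244 in ND5, 381 in ND6 and 334 in CO1 at an unadjusted p under 0.05, and 2, 28, 1 and 0 by DESeq2). ND5 responders had higher heat shock chaperones (median 0.60, 11 of 13 adjusted over the list alone and 0 over all genes, adjusted p = 3.79e-12) and immediate early genes (median 1.15, 10 of 18 adjusted over the list alone and 0 over all genes, adjusted p = 1.08e-10), with adjusted p = 0.245 for both with an estimated correlation. The stress-induced factors Atf3 and Egr1 stood at 2.90 ± 0.59 (adjusted p = 0.236) and 2.82 ± 0.64 (adjusted p = 0.278), and the chaperones Hspa1b and Dnajb1 at 2.01 ± 0.61 and 1.13 ± 0.31. Without ND5 mouse B80, a responder, 118 genes were called, with Atf3 at 3.42, Egr1 at 3.31, Hspa1b at 2.48 and Dnajb1 at 1.49 among them, and without mouse B11 1 gene. Without B69 the chaperone median was 0.32 and Egr1 stood at 1.58, and without B11 the median of immediate early genes was 0.64 and Dnajb1 stood at 0.55. ANT1 responders had higher interferon-stimulated genes (median 0.51, 4 of 21 adjusted over the list alone and 0 over all genes, adjusted p = 1.07e-08, and adjusted p = 0.707 with an estimated correlation), with Gbp3 at 1.67 ± 0.54, the fast myosin-binding protein Mybpc2 at -3.75 ± 1.15 and Slc25a4 at -0.76 ± 0.22 (adjusted p = 0.992 for each). Non-responder A30 had a Myh4 level of 7.92 on the log2 CPM scale, against 4.04 to 4.49 in the other 5 mice, and without it Mybpc2 stood at -2.15. Gbp3 stood at 0.76 without A81, and Slc25a4 at -0.50 without A13 and -1.16 without A43. CO1 responders had lower tendon markers (median -1.63, 5 of 7 adjusted over the list alone and 0 over all genes, adjusted p = 1.54e-06, and adjusted p = 0.825 with an estimated correlation), with Fmod at -1.66 ± 0.60 and Col12a1 at -1.29 ± 0.72 (-0.54 without E50). ND6 responders had higher fatty acid oxidation genes (median 0.17, 0 of 19 in either count, adjusted p = 1.35e-05, and adjusted p = 0.605 with an estimated correlation), with the lipid droplet protein Plin5 at 0.99 ± 0.32 (0.39 without I50) and the interferon-stimulated Isg15 at -1.51 ± 0.55. That list was not called without ND6 mouse I50 (median 0.0533, adjusted p = 0.275) or I59 (median 0.0619, adjusted p = 0.19), and its median was 0.27 without I75 and 0.28 without I63. Without I63 1 gene was called in ND6.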

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

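The tests of position on chromosome 8, of the atrial score, of mouse B80, of Myh4, of tendon markers, of library size and of mouse I59 were chosen after the results were seen, and the splits of the samples before.

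Single libraries stood far from the other 5 of their group in 10 of 96 group values tested, where chance would give 4.8, with Myh4 added to these values after A30 was seen to stand apart. By total counts it was the heart of exercised ANT1 mouse A73 (21.04 M, the others 22.9 to 23.9 M). By mtDNA share it was the soleus of non-exercised ANT1 mouse A82 (47.6%, the others 35.8% to 39.2%) and of exercised ND5 mouse B80 (20.2%, the others 17.8% to 18.6%). By the log2 CPM of Myh4 it was the soleus of exercised ANT1 mouse A30 (7.92, the others 4.04 to 4.49). By that of Myl7 it was the hearts of CO1 mice E42 (5.00, the others 0.09 to 1.25) and E50 (9.06, the others 0.09 to 0.97). By that of Adipoq it was the same 2 hearts, at -0.21 (the others -2.23 to -1.95) and 4.35 (the others -3.54 to -1.60). By that of Ucp1 it was the hearts of exercised ND5 mouse B11 (7.84, the others -3.54 to -2.21) and of E50 (4.39, the others -3.54 to -2.40).

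Strain differences that were not the same in soleus and heart, by a test of the difference itself, numbered 1797 genes for ANT1, 24 for ND5 against ND6, 153 for ND5 against CO1 and 1 for ND6 against CO1. For ANT1 they included Slc25a4 (1.82), mt-Nd5 (0.97), mt-Nd6 (0.98), mt-Co1 (1.30), Kcnk3 (4.87), N4bp1 (1.52), Il15 (4.62), Ndufs8 (0.89), Eda2r (-2.55), Ablim1 (-2.80), Ankrd1 (-3.50) and Col1a1 (-2.21), as log2 values of soleus minus heart. For ND5 against ND6 they included Stmn1 (1.91), Col5a3 (1.97), Mki67 (3.03) and Bmpr1b (-4.03), and for ND5 against CO1 Stmn1 (1.64), Car3 (-7.82), Adipoq (-8.00) and Bmpr1b (-5.50).

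Genes changed in ANT1 hearts gathered on both sides of Slc25a4. Of the called genes with a known position 28.9% (35 of 121, Slc25a4 left out) lay within 50 Mb of it, against 3.59% of the tested genes (486 of 13541, Fisher p = 1.49e-22), which argues against the loss of ANT1 without a role of position for the set as a whole. DNA of the strain in which the gene was targeted, carried along with the allele, could give such a gathering. In soleus the shares were 3.82% and 3.65% (Fisher p = 0.337), and 26 of the 35 near genes and 50 of the 86 elsewhere had changed the same way in soleus (Fisher p = 0.103). Il15, Gsr, Leprotl1, Calr, Scoc, Rnf150, Rnaseh2a and Gdf15 are among the near genes, so their change, in soleus too, cannot be ascribed to the loss of ANT1 from these data. The same holds for the tissue difference of Il15 and of N4bp1, which lies within 50 Mb of Slc25a4 too.

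Genes higher in ND5 than in CO1 hearts went with atrial, adipocyte and red cell markers. The 1458 genes had a median log2 change of 1.33, which was 0.706 with the atrial score as a covariate (8 genes called) and 0.750 without mouse B80 (5 genes called). The heart of B80 had Myh4 at 3.95 on the log2 CPM scale, where the other non-exercised ND5 and CO1 hearts stood at -3.54. Its mtDNA share was 9.23% (the others 15.7% to 28.5%), which points to other tissue in that sample. As causes of the whole difference, atrial tissue and a mixed or mislabelled B80 sample cannot be told apart from an effect of the ND5 mutation. Both medians lay slightly above the bound of 50% of 1.33, while the counts of calls fell below theirs. With atrial, adipocyte and red cell scores together the median was 0.236, with 1 gene called. An effect of the ND5 mutation itself was not tested apart from these.

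Matrix and embryonic myosin genes were higher in ND5 than in ND6 soleus. The matrix list kept a median of 1.398 with Myh4 as a covariate (1.56 without), which argues against fast muscle taken with the soleus as the whole cause. Tendon markers outside the matrix list had a median of 0.416, below that of the matrix list, which argues against tendon as the whole source. Of these 7 markers Thbs4 (1.85 ± 0.39) and Scx (0.80 ± 0.24) were called higher, and the others, from -0.50 to 0.44, were not called. A part from tendon is therefore not excluded. With every soleus library thinned to 10.2 M counts the matrix median was 1.595 and 1549 genes were called, so unequal depth as such did not make the difference. Thinning keeps the proportions of genes within a library, so it cannot test what the lower totals of ND5 may go with. Exercised mice gave 0 genes for this comparison with edgeR (793 at an unadjusted p under 0.05), with or without ND6 mouse I59, so an effect of the mutation stays a hypothesis, found and tested on the same mice.

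Other splits of the same samples into groups of the same sizes, 100 per comparison with the real one included, were used to ask whether chance can be excluded for counts of genes. For counts of called genes it can be excluded for ANT1 in soleus (6653 genes, highest other split 1949, 1 of 100 as large), ND5 against ND6 in soleus (2017, highest other 1983, 1 of 100) and the tissue difference of ANT1 (1797, highest other 1716, 1 of 100). It can be excluded as well for ANT1 against each strain in soleus (3314, highest other 0, 1 of 100) and in heart (28, highest other 0, 1 of 100). For ND5 against CO1 in heart (1760, highest other 1914, 2 of 100) and its tissue difference (153, highest other 734, 4 of 100) chance can be excluded only if each is taken alone. With as many results tested, some shares as small arise by chance. Every result for which chance is excluded only when taken alone therefore stays open. The counts of ND5 against CO1 depend on the fit. In heart 5 genes were called without mouse B80, 0 with the compared groups only and 0 in exercised mice. Without the filter on low counts 1032 were called there, and with both arms averaged 3492. For the tissue difference 0 were called without B80, with the compared groups only, and in limma voom with or without the block. DESeq2 called 331 and the fit without the filter 70. Chance cannot be excluded for ANT1 in heart (144, highest other 2361, 13 of 100), the tissue difference of ND5 against ND6 (24, highest other 3475, 26 of 100) or that of ND6 against CO1 (1, highest other 3, 7 of 100). In ANT1 heart and in the tissue differences of ND5 against ND6 and CO1, other splits called several times as many genes as the real one, which points to a structure of the samples beside strain.

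Where edgeR called 0 genes, the splits compared counts at an unadjusted p under 0.05. For ND6 against CO1 in heart chance can be excluded for that count only if it is taken alone (2164, highest other 2399, 4 of 100), and among as many results it stays open. It cannot be excluded for ND5 against CO1 in soleus (3080, highest other 4606, 9 of 100), ND6 against CO1 in soleus (286, highest other 1196, 69 of 100) or ND5 against ND6 in heart (1025, highest other 6107, 61 of 100). Nor can it for training in soleus, in ANT1 (350, highest other 2739, 85 of 100), ND5 (2086, 4546, 13 of 100), ND6 (688, 1973, 36 of 100), CO1 (268, 1279, 49 of 100), on average (536, 2961, 58 of 100) or by strain (984, 2408, 26 of 100). The same holds for training in heart, in ANT1 (353, 5147, 64 of 100), ND5 (793, 7985, 81 of 100), ND6 (680, 2536, 40 of 100), CO1 (287, 1316, 49 of 100), on average (538, 6259, 52 of 100) and by strain (644, 5773, 62 of 100), and for responders on average (622, 1762, 39 of 100). In most of these the highest other split gave several times the real count, which points to a structure of the samples that these groups do not follow. Within a strain, 3 responders and 3 non-responders make 10 splits, too few for a share under 0.05. The counts there were 594 in ANT1 (highest other 1254, 6 of 10 as large), 1244 in ND5 (1503, 3 of 10), 381 in ND6 (1858, 8 of 10) and 334 in CO1 (718, 6 of 10).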

How the results depend on the processing

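Settings chosen after seeing the data were the Myh4, atrial and 3-score covariates, and the fits without A81 and A82, without mtDNA-encoded genes, without the block in limma voom and without each library in turn. The strain comparisons that replaced those with the control strain were chosen after the column names were seen. Of 303 alternative counts of genes 227 stayed within 1.5 times the reported count and 76 moved further. Of 1817 alternatives for named genes 1618 kept direction and side of the threshold, 126 lost the call, 40 gained it and 33 reversed, and of 810 for gene lists these numbers were 656, 124, 12 and 18. ANT1 against the mtDNA strains in soleus ranged from 5746 genes (Myh4 as a covariate) to 8394 (both arms averaged). The alternative with the Xist level was not run, because Xist was near 0 in all libraries. At these depths (10.2 M counts in the smallest soleus library, 19.7 M in heart) edgeR recovered 93% to 96% of simulated 2-fold changes for strain and training in soleus and 77% to 85% in heart, and 98% and 78% for responders on average and in ND5. For the values that follow the cause was not tested, except that fits on fewer libraries and tests without the filter on low counts differ in what was tested.

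In exercised mice, ND5 against ND6 in soleus gave 0 genes, ANT1 in heart 751, ND5 against CO1 in heart 0, ND6 against CO1 in heart 89, and ANT1 against each strain in heart 72. Directions reversed for ND5 against ND6 in soleus (Nnt 0.22, Col5a3 -0.0280, Serpinb1a -0.0243, Stmn1 -0.55, Col1a1 -0.12, Lox -0.28, Myh3 -1.32, Myh8 -0.74, Chrng -0.92, Acadm 0.00475 and Myh13 0.0345), ND5 against CO1 in heart (Grip2 -0.23, Acta2 -0.66 and Pdk4 0.51), ND6 against CO1 in soleus (Col1a1 0.78), ND5 against ND6 in heart (mt-Nd5 0.17 and Eln -0.83) and ND6 against CO1 in heart (mt-Nd6 -0.26). List medians reversed for slow-fibre genes of ANT1 soleus (0.0449), for matrix (-0.0343), atrophy (-0.0737) and tendon (-0.23) lists of ND5 against ND6 in soleus, for smooth muscle markers of ND5 against CO1 in heart (-0.44), and for the matrix list of ND6 against CO1 in soleus (0.34) and of ND5 against ND6 in heart (-0.56). With both arms averaged the counts were 557 for ND5 against ND6 and 646 for ND5 against CO1 in soleus, 1977 for ANT1, 1 for ND5 against ND6, 3492 for ND5 against CO1 and 2681 for ND6 against CO1 in heart, and 5520 in soleus and 274 in heart for ANT1 against each strain. mt-Nd6 for ND6 against CO1 in heart (-0.11) and the list medians of the integrated stress response in ANT1 soleus (-0.00692) and of tendon markers for ND5 against ND6 in soleus (-0.13) reversed there.

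With DESeq2 the counts were 410 for ND5 against CO1 and 1 for ND6 against CO1 in soleus, 1, 51 and 2 for training of ANT1, ND5 and ND6 in soleus, and 1 for ND5 against ND6 and 96 for ND6 against CO1 in heart. They were 1 each for heart training of ANT1, ND5, CO1, on average and by strain, 2, 28 and 1 for responders of ANT1, ND5 and ND6, and 120, 331 and 17 for the tissue difference of ND5 against ND6, ND5 against CO1 and ND6 against CO1. Without the filter on low counts they were 3 for ND5 against CO1 and 1 for training of ANT1 in soleus, 1032 for ND5 against CO1 and 8 for training of ND5 in heart, 28, 197, 5, 5 and 17 for responders of ANT1, ND5, ND6, CO1 and on average, and 1186, 11 and 70 for the tissue difference of ANT1, ND5 against ND6 and ND5 against CO1. With the compared groups only, they were 1032 for ND5 against ND6 in soleus, 68 for ANT1, 0 for ND5 against CO1 and 1 for ND6 against CO1 in heart, 8 for ANT1 against each strain in heart, and 6, 0 and 0 for the tissue difference of ND5 against ND6, ND5 against CO1 and ND6 against CO1. The stress response median of ANT1 soleus was -0.00182 there.

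With Myh4 as a covariate, soleus gave 1150 genes for ND5 against ND6, 5 for ND5 against CO1 and 3 for training of ND5. mt-Co1 for training of ND6 (0.00376) and the stress response median of ANT1 (-0.0349) reversed. Without A81 and A82, soleus gave 10 genes for ND5 against CO1 and 1 for training of ANT1, and the stress response median was -0.0128. With the atrial score, heart gave 1063 genes for ANT1, 8 for ND5 against CO1, 1 for ND6 against CO1 and 73 for ANT1 against each strain, and the tissue difference gave 67 for ND5 against ND6 and 0 for ND5 against CO1. Reversed there were Myl7 (-0.40) and the atrial median (-0.21) for ANT1, mt-Nd5 for ND5 against CO1 (0.0229), mt-Co1 for ND6 against CO1 (0.20), mt-Nd6 for training of ND6 (0.0636), mt-Co1 for training on average (0.0248) and Nnt for the tissue difference of ANT1 (-0.23). With the atrial, adipocyte and red cell scores, heart gave 1732 genes for ANT1, 1 for ND5 against CO1 and 120 for ANT1 against each strain. Reversed were Myl7 (-0.43) and the atrial median (-0.22) for ANT1, mt-Nd5 (0.0847), mt-Nd6 (0.0525) and the brown adipocyte (-1.48) and red cell (-0.0328) medians for ND5 against CO1, and mt-Co1 for ND6 against CO1 (0.36). The scores contain Myl7 and other atrial, adipocyte and red cell markers, so those reversals follow from the fit.

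Without mouse B80 the counts were 5 for ND5 against CO1 in heart, 118 for responders of ND5 and 0 for the tissue difference of ND5 against CO1, and mt-Nd5 reversed for heart training of ND5 (-0.16). With each responder or non-responder left out in turn, ND5 gave 0 to 118 genes (118 without B80 and 1 without B11), ND6 0 to 1 (1 without I63), and ANT1, CO1 and the average 0 to 0. With each library of the strain and training comparisons left out in turn, counts ranged from 5930 to 6792 for ANT1, 442 (B70) to 3293 (B10) for ND5 against ND6 and 0 to 1685 (B10) for ND5 against CO1 in soleus, 0 to 272 lower and 0 to 149 higher (B10) for training of ND5 in soleus, and 68 (A72) to 242 (A80) for ANT1, 5 (B80) to 3247 (B5) for ND5 against CO1 and 0 to 27 (E75) for ND6 against CO1 in heart. With the mouse as a block in limma voom, the tissue difference gave 0 genes for ND5 against CO1 and 0 for ND6 against CO1, and Nnt reversed (-0.14). Against edgeR the blocked fit moved no other count by over 1.5 times (1237 for ANT1 and 23 for ND5 against ND6). limma voom with no block gave 1227, 4, 0 and 0 genes for ANT1, ND5 against ND6, ND5 against CO1 and ND6 against CO1, with Nnt at -0.14, so between the voom fits the block moved ND5 against ND6 from 4 to 23. The carrier list of ANT1 soleus (median 0.41) pointed down with an estimated correlation (adjusted p = 0.944) and in the rotation test (adjusted p = 8.43e-20). The rotation test, which does not compare a list with other genes, passed 31 of 37 lists for ANT1 and 21 of 37 for ND5 against ND6 in soleus. In heart it passed 2 of 41 for ANT1 and 18 of 41 for ND5 against CO1. For training it passed 1 list, in ND6 heart, and for responders 0.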

Other observations

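The tests of relations within groups were chosen after the results were seen. In ANT1 soleus, lists beyond those described moved too. Of 21 glycolysis genes 12 rose and 3 fell against the mtDNA strains (median log2 fold change 0.26, adjusted p = 0.00685, and adjusted p = 0.38 with an estimated correlation). Of 14 PPAR targets 8 rose and 1 fell (median 0.52, adjusted p = 0.00887), of 12 genes of mitochondrial fusion and fission 8 rose and 1 fell (median 0.24, adjusted p = 0.00881), and of 19 antioxidant genes 8 rose and 3 fell (median 0.13, adjusted p = 0.0383), with adjusted p = 0.38 for each with an estimated correlation. Of 13 fetal and load-responsive cardiac genes 1 rose and 9 fell (1 and 10 over the list alone, median -0.92, adjusted p = 0.00469, and adjusted p = 0.289 with an estimated correlation). In ANT1 heart, neutrophil markers (median 1.93, 0 of 5 called and 3 over the list alone, adjusted p = 0.0036) and immediate early genes (median 0.65, 0 of 18 called and 1 over the list alone, adjusted p = 0.000249) were higher by the preset test, with adjusted p = 0.741 for both with an estimated correlation.

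Within groups of the mtDNA strains, soleus libraries with more matrix transcripts had more embryonic myosin and a lower mtDNA share. Over 36 libraries the matrix score had an r of 0.905 with the mean level of Myh3 and Myh8 (permutation p = 1e-05, the smallest possible, rho 0.896, r 0.880 without the 2 farthest libraries, adjusted p = 4e-05) and of -0.561 with the mtDNA share (permutation p = 0.00231, rho -0.516, r -0.519 without the 2 farthest, adjusted p = 0.00462), of 4 relations tested. In the 12 ANT1 libraries r was -0.0595 with embryonic myosin (permutation p = 0.863, rho -0.353, r 0.325 without the 2 farthest, adjusted p = 0.863) and 0.536 with the mtDNA share (permutation p = 0.0857, rho 0.146, r -0.0975 without the 2 farthest, adjusted p = 0.114). This is in line with muscle repair or regrowth differing between single mice within a strain, which was tested only as far as these relations, whose r of 0.905 and -0.561 do not show what differed.

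The 1st principal component held 44.4% of the variance in soleus, with an absolute correlation of 0.878 with the mtDNA share. In heart it held 52.6%, with absolute correlations of 0.942 with the atrial score and 0.751 with the mtDNA share. The signs were not kept, so these values do not say whether the score and the share ran the same way.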
